A study of Bos grunniens and Bos grunniens x Bos taurus and Bos taurus with 18 samples.

How the data were processed

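Total RNA of cerebrum and cerebellum from 3 yak, 3 yakow and 3 cattle aged 4.5 years was extracted with TRIzol, depleted of ribosomal RNA and sequenced on an Illumina instrument, per the labels' protocols. Each of the 9 animals gave 1 library per tissue, which makes 6 groups of 3 and 18 libraries. Reads were trimmed with fastp 0.19.8, aligned with HISAT2 2.1.0 and assembled with StringTie 1.2.3, per the submitters' processing notes. Per the file headers, StringTie was run on each library with 1 merged annotation of all samples, and the alignments lay in a folder named for a yak reference. All 3 species were therefore measured on the same transcript models, and the genome build is not given in the sources used here. Whether a locus without a name is coding is not given in the sources used here either, and positions of loci are not printed. The headers also name the animal and the lane. Yak cerebrum came from lane 4, yak libraries labelled cerebellum from lane 2, yakow cerebrum from lane 3, yakow libraries labelled cerebellum from lane 4, cattle cerebrum from lanes 3, 4 and 4 and cattle cerebellum from lanes 4, 2 and 2, and the flow cell is not known.

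The deposited values give 3 units per transcript. TPM, as deposited by the authors, is scaled by StringTie to a fixed total per library. FPKM, as deposited by the authors, is scaled to transcript length and aligned fragments. Coverage, as deposited by the authors, is the mean depth per base of each transcript. Transcript TPM was summed per locus of the merged annotation over 41960 loci. The sums were rescaled by median-of-ratios factors between 0.6662 and 1.174, and loci with at least 1 TPM in at least 3 libraries were kept, which left 29412. Values were taken as log2(TPM + 1). The files hold no read counts, so counting error is not known. Coverage times transcript length gave aligned gigabases on transcripts. These were 9.15, 9.57 and 9.72 in yak cerebrum, 10.1, 9.91 and 8.76 in the yak libraries labelled cerebellum, 7.59, 8.93 and 8.9 in yakow cerebrum and 8.22, 9.79 and 7.45 in the yakow libraries labelled cerebellum. They were 7.95, 7.42 and 8.06 in cattle cerebrum and 9.11, 9 and 7.75 in cattle cerebellum. Between 17884 and 25705 loci reached 1 TPM per library. The 10 most abundant loci held 20.6% to 48.3% of TPM, the highest share in cattle cerebellum 1, and loci without a name held 28.3% to 55.8%.

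A linear model with 6 group means was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all tested loci, and an adjusted p below 0.05 was a call. The comparisons were cerebellum against cerebrum in each species and over the 3 species, each pair of species within each tissue, and the interaction of species and tissue by a moderated F test. The position of the yakow was its difference from cattle over that of yak from cattle, for loci called in one tissue and measured in the other. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

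A set of 37 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and the alternatives other than those said below to be later. Of these, 31 had at least 3 tested loci and were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists cover hypoxia targets, the hypoxia-inducible factor pathway, altitude candidates, glycolysis, nuclear genes of the respiratory chain, antioxidant, heat shock, immediate early, interferon, antigen presentation, glutamate receptor, GABA receptor, calcium signalling, globin and ribosomal protein genes. They also cover markers of granule neurons, Purkinje cells, cerebellar patterning, cortical excitatory neurons, telencephalic interneurons, striatum, thalamus, choroid plexus, ependyma, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, mural cells and neurons at large. Mitochondrially encoded genes had 1 tested locus, erythroid and hypothalamic or pituitary genes 2 each, and sex-linked, histone and small structural RNA genes 0, so these lists were not tested as sets.

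Genes were named by a rule. Among genes with a name that were called, with the 3 libraries of a group all above the 3 of the other (all 9 above all 9 for tissue over species) and a mean of at least 5 TPM in the higher group, the 5 largest log2 fold changes in each direction were taken. For each list called in a comparison, and for the lists on hypoxia, glycolysis, respiration, globins and cell types, up to 3 called members were added, or the member with the highest mean where none was called. For the interaction the 10 smallest p-values among named genes with at least 5 TPM in a group were taken. The text gives the few of these that matter in full, and some genes that the rule takes are not reported here.

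Cerebrum and cerebellum libraries with the same number came from the same animal, per the file headers. Their deviations from group means correlated at 0.148, 0.102 and 0.17 in yak, 0.14, 0.266 and 0.234 in yakow and 0.056, 0.187 and -0.027 in cattle. A fit with the animal as a block was run as an alternative. Other alternatives were TPM and FPKM without rescaling, quantile normalization, a pseudocount of 0.1, other filters, limma-voom on reads estimated from coverage at an assumed read length of 150, array weights, fits of the compared groups alone, a fold threshold, named genes only and each library left out in turn. Chosen after the data were seen were annotated transcripts only, lane as a covariate, lane 4 alone, a fit without the 6 yak and yakow libraries labelled cerebellum, set tests among symbols, and the position over symbols or in the same tissue.

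The procedure was tested on simulated data for the comparison of yak and cattle cerebrum over 28044 loci. Of 50 loci changed at each size, 0% were recovered at a fold of 1.5, 16% at 2, 82% at 4 and 90% at 8. Of 99 calls 5 were false (5.05%). The changed loci all had a mean of at least 5 TPM, and the noise was normal and independent between loci. Far fewer loci were changed than were called in the real comparison, so these shares need not hold there.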

Results

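RNA-seq was carried out on cerebrum and cerebellum of yak (Leiwuqi Yak, Bos grunniens), cattle (Sanjiang Cattle, Bos taurus) and yakow (Zang Yakow, the cross of Bos grunniens with Bos taurus). The 18 libraries fell into 6 groups of 3 animals, and each of the 9 animals, aged 4.5 years, gave 1 library per tissue. The series asks which coding and long non-coding RNAs of the brain bear on life at high altitude, which yak are native to. The libraries held 9.47 to 13.4 gigabases of aligned sequence, of which 72.8% to 80.4% lay on assembled transcripts. Yak cerebrum was covered by 9.15 to 9.72 gigabases on transcripts and cattle cerebrum by 7.42 to 8.06. Of 41960 loci, 29412 reached 1 TPM in at least 3 libraries and were tested. Among these, 11317 carried a gene symbol, 2229 a numbered locus name, 1053 the names of several genes and 14813 no name. Values below are rescaled TPM as mean ± SD (n = 3 animals), log2 fold changes are on the log2(TPM + 1) scale, and adjusted p-values are from limma.

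Genes known to mark cerebellar granule cells were abundant in cattle cerebellum and far lower in every library of yak and yakow, those labelled cerebellum included. GABRA6, a GABA-A receptor subunit of granule cells, stood at 276.8, 275 and 304.7 TPM in the cattle cerebellum libraries and at no more than 0.1601 TPM in any other library. The mean level of the 13 granule neuron markers was 6.88, 6.69 and 6.37 log2 units in cattle cerebellum and between 1.71 and 2.5 elsewhere, and that of the 16 Purkinje cell markers 5.86, 5.63 and 5.81 against 2.08 to 3.1. The mean level of the 8 cerebellar patterning genes was 2.03, 1.97 and 2.07 in cattle cerebellum, 1.98 in yak labelled cerebellum 2, 1.95 in yakow labelled cerebellum 1 and between 0.67 and 1.07 elsewhere. Yak labelled cerebellum 1 and 3 carried striatal transcripts. DRD1, a dopamine receptor of striatal projection neurons, was at 146, 28.2 and 92.4 TPM in the 3 yak libraries labelled cerebellum, and the mean of 10 striatal markers was 7.99, 3.57 and 7.59. SLC17A6, a vesicular glutamate transporter on the list of thalamic markers, was at 90.8 TPM in yak labelled cerebellum 2 and 85.1 TPM in yakow labelled cerebellum 1, the 2 libraries with patterning genes at the cattle cerebellum level. The mean level of the 17 cortical excitatory markers was 1.69, 5.19 and 4.54 log2 units in the yakow libraries labelled cerebellum, against 2.97, 2.6 and 2.72 in cattle cerebellum. Across all tested loci the yak libraries labelled cerebellum correlated with yak cerebrum at a mean r of 0.931 and with cattle cerebellum at 0.822, and the yakow libraries labelled cerebellum with yakow cerebrum at 0.928. Groups are kept as labelled throughout, and these 6 libraries are called the libraries labelled cerebellum.

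**Figure D1:**
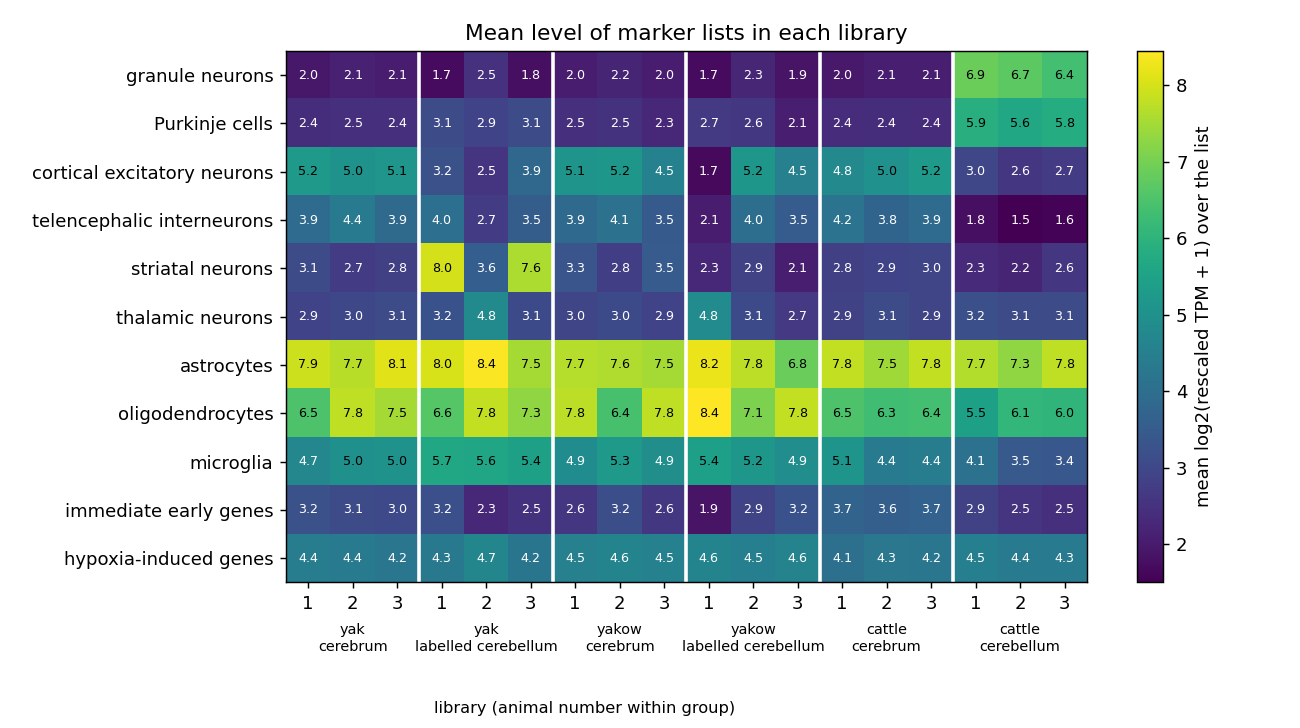
Heat map of the mean log2(rescaled TPM + 1) of 11 marker lists (vertical axis) in each of the 18 libraries (horizontal axis, grouped by species and labelled tissue). The granule neuron list is at 6.88, 6.69 and 6.37 in the 3 cattle cerebellum libraries and at or below 2.5 elsewhere, and the striatal list at 7.99 and 7.59 in yak labelled cerebellum 1 and 3.

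The comparison of cerebellum with cerebrum in cattle asks which genes separate these brain parts. Granule and Purkinje cell genes were far higher in cerebellum. GABRA6 rose from 0.0868 ± 0.0809 to 285.5 ± 16.7 TPM, and FAT2, a protocadherin of granule cell parallel fibres, from 1.26 ± 0.479 to 482.4 ± 57.7. CBLN1, the organiser of parallel fibre synapses, went from 4.22 ± 0.719 to 923.7 ± 304.1 TPM, and CALB1, the calcium buffer of Purkinje cells, from 0.0322 ± 0.0077 to 260.3 ± 56.8. GRIN2C, an NMDA receptor subunit of granule cells, went from 0.38 ± 0.0719 to 199.5 ± 40.6 TPM. In the other direction, SST, the peptide of cortical interneurons, fell from 259.4 ± 23.8 to 0.305 ± 0.436 TPM. NRGN, a calmodulin-binding protein of forebrain neurons, fell from 1527 ± 836.4 to 10.4 ± 7.42 TPM. DDN, a postsynaptic protein of the same neurons, fell from 171.3 ± 61.5 to 0.425 ± 0.139. ENC1, an actin-binding protein of cortical neurons, fell from 509.1 ± 111.6 to 5.51 ± 0.973 TPM. CCK, the peptide of cortical neurons, fell from 441.1 ± 289.8 to 5.73 ± 1.85 TPM (adjusted p = 0.0183), a call that was lost without cattle cerebrum 1 (0.0604), cerebrum 3 (0.0554) or cerebellum 2 (0.0532).

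All 13 granule neuron markers rose in cattle cerebellum, 13 also when adjusted over the list alone, and the list stood above the other loci (camera adjusted p = 3.03e-23, adjusted p = 5.67e-05 with an estimated correlation). Of 16 Purkinje markers 13 rose, 14 when adjusted over the list alone (adjusted p = 7.64e-20, and 5.67e-05 with an estimated correlation), among them PCP2 and ARHGEF33 by 5.29 ± 0.24 and 5.22 ± 0.52 log2 units (SE). EN1 and PAX2, transcription factors that pattern the midbrain and hindbrain, were listed at 0 in the 3 cattle cerebrum libraries and stood at 9.97 ± 3.1 and 8.84 ± 2.1 TPM in cerebellum. The patterning list had 4 members up and 2 down of 8 (adjusted p = 0.0521). Of 17 cortical excitatory markers 11 fell, 11 when adjusted over the list alone (adjusted p = 6.28e-05, and adjusted p = 0.439 with an estimated correlation). CAMK2A, the kinase of forebrain synapses, fell by -4.88 ± 0.95 log2 units. Of 14 telencephalic interneuron markers 7 fell, 10 down and 1 up when adjusted over the list alone (adjusted p = 0.000882, and adjusted p = 0.439 with an estimated correlation).

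Immediate early genes, which neuronal activity induces, were lower in cattle cerebellum than in cerebrum. Of 20 such genes 9 fell, 10 down and 1 up when adjusted over the list alone (adjusted p = 0.00533, and adjusted p = 0.439 with an estimated correlation). ARC, a regulator of synaptic receptor traffic, fell from 98.6 ± 39.7 to 1.33 ± 0.541 TPM. EGR2, a zinc finger transcription factor, fell from 7.88 ± 3.28 to 0.268 ± 0.181. Among 11 astrocyte markers SLC1A2, the main glutamate transporter of forebrain astrocytes, fell from 998.7 ± 115.5 to 54.7 ± 17 TPM. GDF10, a secreted factor of Bergmann glia, rose from 8.45 ± 3.58 to 42.6 ± 11.1 TPM. The astrocyte list was not called (adjusted p = 0.718, median 0.22 and mean -0.12). Of 7 oligodendrocyte precursor markers 2 fell, 6 when adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.439 with an estimated correlation). Of 14 oligodendrocyte markers MBP, the myelin basic protein, alone fell, from 6896 ± 654.2 to 2746 ± 538.2 TPM (list adjusted p = 0.107, and 0.0274 with the animal as a block). The list of 8 antigen presentation genes was not called (adjusted p = 0.143, and 0.0304 with the animal as a block). Of 11 microglia markers 2 fell, 3 when adjusted over the list alone (adjusted p = 0.0123, adjusted p = 0.439 with an estimated correlation, and 0.0561 without cerebellum 3). Of 14 endothelial markers 6 fell and 1 rose, 7 down and 1 up when adjusted over the list alone (adjusted p = 0.0468, and adjusted p = 0.607 with an estimated correlation). The endothelial receptor TIE1 rose from 12 ± 0.733 to 70.7 ± 4.45 TPM and EGFL7, a secreted vessel protein, fell from 55.2 ± 1.72 to 19.2 ± 1.65. That list lost its call without cerebrum 1 (0.0677) or 3 (0.0723) or cerebellum 2 (0.11) or 3 (0.129). The 12 mural and fibroblast markers had 2 members down (adjusted p = 0.0261, adjusted p = 0.644 with an estimated correlation, and 0.0547 without cerebrum 2 or 0.244 without cerebellum 3). TAGLN, a smooth muscle actin-binding protein, fell by -1.31 ± 0.21 log2 units. The 23 interferon genes had 3 members down and 1 up, 5 down and 1 up when adjusted over the list alone (adjusted p = 0.0381, and adjusted p = 0.764 with an estimated correlation). That call was lost (0.133, 0.11 or 0.206) without cerebrum 1, cerebellum 2 or cerebellum 3.

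No list of oxygen response or energy metabolism was called between the cattle tissues, though single members were. Of 25 hypoxia targets 4 rose in cerebellum (list adjusted p = 0.135). ANKRD37, a target of hypoxia-inducible factor, rose from 3.73 ± 0.917 to 11.7 ± 2.45 TPM. VLDLR, a lipoprotein receptor, rose from 12.6 ± 3.4 to 27.5 ± 3.71. Of 13 genes of the hypoxia-inducible factor pathway 3 rose and 2 fell (list adjusted p = 0.833). HIF1A, the oxygen-regulated subunit of that factor, rose from 81.4 ± 17.9 to 175.5 ± 23.7 TPM, and ARNT2, a neuronal partner of HIF1A, fell by -1.52 ± 0.36 log2 units, a direction that turned to 1.44 with annotated transcripts only. Of 18 altitude candidate genes 2 rose and 2 fell (adjusted p = 0.915). PFKL, the liver-type phosphofructokinase, was the 1 of 17 glycolysis genes that rose, from 60.1 ± 6.37 to 157.7 ± 40.1 TPM (list adjusted p = 0.135), and 2 of 45 nuclear genes of the respiratory chain rose (0.149). The oxygen-binding globins NGB and MB fell by -2.62 ± 0.6 and -1.55 ± 0.27 log2 units, NGB from 29.9 ± 10.7 to 3.93 ± 1.2 TPM (list of 3 globins, adjusted p = 0.0885). In total 2424 loci were higher in cattle cerebellum and 2753 lower, with 1226 and 944 among symbols, and with TPM as deposited the split was 1199 to 3799, since that scaling moves the median of all loci from -0.044 to -0.27. Cerebrum and cerebellum came in part from different lanes, and the count was 5177 over all lanes, 990 within lane 4 and 2290 with lane as a covariate. Lane 4 held 2 of the cerebrum libraries and 1 of cerebellum, whose spread is assumed to be that of the other groups.

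The same comparison in yak set the libraries labelled cerebellum, whose granule and Purkinje markers lay far below those of cattle cerebellum, against cerebrum, and so its direction is that of the labels. CDHR1, a protocadherin of olfactory and retinal neurons, stood at 3.53 ± 0.435 TPM in cerebrum and 282.1 ± 234.6 in the libraries labelled cerebellum (log2 fold change 5.45 ± 0.59 SE, adjusted p = 0.00085). SCGN, a calcium-binding protein of interneurons, was at 0.257 ± 0.231 and 40.9 ± 45.7 TPM (adjusted p = 0.00176), and SLC5A7, the choline transporter of cholinergic neurons, at 0.0292 ± 0.0085 and 34.9 ± 43.5 TPM (adjusted p = 0.00269). DRD2, a dopamine receptor of striatal neurons, was at 0.84 ± 0.549 and 131.3 ± 105.6 TPM (adjusted p = 0.0115), a call lost without yak cerebrum 2 (0.0608), cerebrum 3 (0.056) or labelled cerebellum 1 (0.0599). SLC30A3, the zinc transporter of cortical synapses, was at 42.4 ± 9.56 TPM in cerebrum and 3.84 ± 1.13 in the libraries labelled cerebellum (adjusted p = 0.0115), a call lost without cerebrum 2 (0.0636) or labelled cerebellum 1 (0.0599). Of 10 striatal markers 3 rose, 9 when adjusted over the list alone (adjusted p = 2.77e-17, and adjusted p = 0.125 with an estimated correlation). Of 17 cortical excitatory markers 1 fell, 8 when adjusted over the list alone (adjusted p = 2.77e-11, and adjusted p = 0.236 with an estimated correlation). That gene was FEZF2, a transcription factor of deep-layer cortical neurons, at -3.19 ± 0.6 log2 units (adjusted p = 0.0302, and 0.0632 with the animal as a block). Its adjusted p was 0.105, 0.103 or 0.1 without cerebrum 1, 2 or 3, and 0.139 without labelled cerebellum 1.

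Further lists called between the yak tissues moved with few or no called members. The 7 ependymal markers (adjusted p = 3.96e-05, and adjusted p = 0.275 with an estimated correlation) and 64 ribosomal protein genes (2.4e-05, and adjusted p = 0.837 with an estimated correlation) stood above the other loci in the libraries labelled cerebellum. So did 11 microglia markers (0.00115, and adjusted p = 0.275 with an estimated correlation) and 16 Purkinje markers (0.00842, and adjusted p = 0.236 with an estimated correlation). These 4 lists had 0 members called by limma, and 4, 0, 1 and 2 when adjusted over the list alone. Interferon genes (0.00842, and 0.0578 without cerebrum 3 or 0.159 without labelled cerebellum 1) and antigen presentation genes (0.038, and 0.383, 0.195 and 0.205 without cerebrum 3 and labelled cerebellum 1 and 2) did so too. Both had adjusted p = 0.815 with an estimated correlation, and 2 and 0 members passed when adjusted over the list alone. Against symbols alone the interferon, antigen presentation and Purkinje calls ended (0.0983, 0.166 and 0.0894). Without labelled cerebellum 2, the calls were lost for the thalamic list (0.00396 to 0.301), GABA receptors (0.00842 to 0.296, lower) and immediate early genes (0.00576 to 0.14, lower). With an estimated correlation these 3 lists had adjusted p = 0.459, adjusted p = 0.668 and adjusted p = 0.515, and 2, 2 and 1 members passed when adjusted over the list alone. The total was 120 loci, 68 higher and 52 lower in the libraries labelled cerebellum, and 38 with the animal as a block. Leaving out yak cerebrum 1, 2 or 3 left 44, 38 or 33 loci, and leaving out labelled cerebellum 1, 2 or 3 gave 31, 515 or 72. Yak cerebrum was sequenced on lane 4 and the yak libraries labelled cerebellum on lane 2, so no value within a lane exists, and 195 loci were called with lane as a covariate.

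In yakow no locus passed the test between the libraries labelled cerebellum and cerebrum (limma, 0 at adjusted p below 0.05, smallest adjusted p = 0.421), 990 loci had an unadjusted p below 0.05, and voom also called 0. With the animal as a block 2 were called, without yakow cerebrum 2 or labelled cerebellum 2 likewise 2, without cerebrum 3 it was 1, and 12 were called with lane as a covariate. HIF1A was at 88.3 ± 3.4 and 90.3 ± 18.4 TPM, and NGB at 17.1 ± 2.58 and 18.9 ± 6.17. The cortical list, with CAMK2A at 1374 ± 266.3 and 1094 ± 909.5 TPM, was lower in the libraries labelled cerebellum (adjusted p = 3.03e-06, adjusted p = 0.692 with an estimated correlation, and 0.605 without labelled cerebellum 1). The ependymal list was also lower (adjusted p = 0.00041, and adjusted p = 0.692 with an estimated correlation). Calcium signalling genes (0.00041), GABA receptors (0.00278), interneuron markers (0.0155), striatal markers (0.0293) and respiratory chain genes (0.0293) were lower and oligodendrocyte markers (0.0293) higher, each at adjusted p = 0.79 with an estimated correlation. Against symbols alone the interneuron, striatal and respiratory calls ended (0.117, 0.14 and 0.27). Each of these 6 lists lost its call without some single library, and no member of any passed when adjusted over the list alone. Without labelled cerebellum 1 the calcium, GABA, interneuron, striatal and oligodendrocyte lists stood at 0.5, 0.481, 0.844, 0.0626 and 0.9, and without cerebrum 2 calcium, GABA, interneuron, respiratory and oligodendrocyte lists at 0.158, 0.0753, 0.157, 0.352 and 0.967, the oligodendrocyte list turning to lower. The striatal list was also lost without cerebrum 1 (0.11), cerebrum 3 (0.135) or labelled cerebellum 3 (0.181), and the respiratory list without cerebrum 1 (0.439) or labelled cerebellum 3 (0.11, turning to higher).

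Averaged over the 3 species, granule and Purkinje markers stood above the other loci in cerebellum as labelled. In yak and yakow taken alone the granule list was not called (adjusted p = 0.841 and 0.53), and the tissue difference differed among species for 12 of its 13 members. Of 13 granule markers 10 rose, 12 when adjusted over the list alone (adjusted p = 8.22e-05 with an estimated correlation). Of 16 Purkinje markers 12 rose, 13 when adjusted over the list alone (adjusted p = 7.82e-05 with an estimated correlation). Of 17 cortical markers 9 fell, 13 when adjusted over the list alone (adjusted p = 1.76e-13, and adjusted p = 0.138 with an estimated correlation). Of 20 immediate early genes 6 fell, 8 when adjusted over the list alone (adjusted p = 0.000141, and adjusted p = 0.337 with an estimated correlation). Of 8 patterning genes 4 rose and 1 fell, 5 up and 2 down when adjusted over the list alone (adjusted p = 0.00789, and adjusted p = 0.607 with an estimated correlation). Of 14 interneuron markers 5 fell, 6 down and 1 up when adjusted over the list alone (0.000537, and adjusted p = 0.418 with an estimated correlation). Called genes with a name and at least 5 TPM in a tissue had all 9 libraries above the other 9 in 4 cases. MAP3K1, a signalling kinase, and HPS3, a protein of lysosome-related organelles, were higher by 0.47 ± 0.11 and 0.42 ± 0.11 log2 units. KIAA1522 and SDK1, a synaptic adhesion protein, were lower by -1.01 ± 0.13 and -0.88 ± 0.16. With annotated transcripts only, MAP3K1 and SDK1 turned to -0.21 and 0.32. In all 782 loci were higher and 995 lower, a split of 393 to 1504 with TPM as deposited, and 110 loci were called with lane as a covariate. GABA receptors and mural markers were not called without the animal as a block (adjusted p = 0.0916 and 0.0541) and were with it (0.0492 and 0.0126). The striatal call (0.0181, and adjusted p = 0.789 with an estimated correlation) was lost without yak labelled cerebellum 1 (0.127) or 3 (0.0875) or yakow labelled cerebellum 2 (0.0587), and against symbols alone (0.0758). The thalamic call (0.00789, and adjusted p = 0.492 with an estimated correlation) was lost without yak labelled cerebellum 2 (0.0698). The tissue difference itself differed among species at 1870 loci, 792 of them with a symbol, led by GABRA6 (adjusted p = 2.01e-11) and FAT2 (2.07e-10). That count was 1143 without cattle cerebrum 1, 1072 without cattle cerebrum 2 and 1183 without cattle cerebellum 2.

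**Figure D2:**
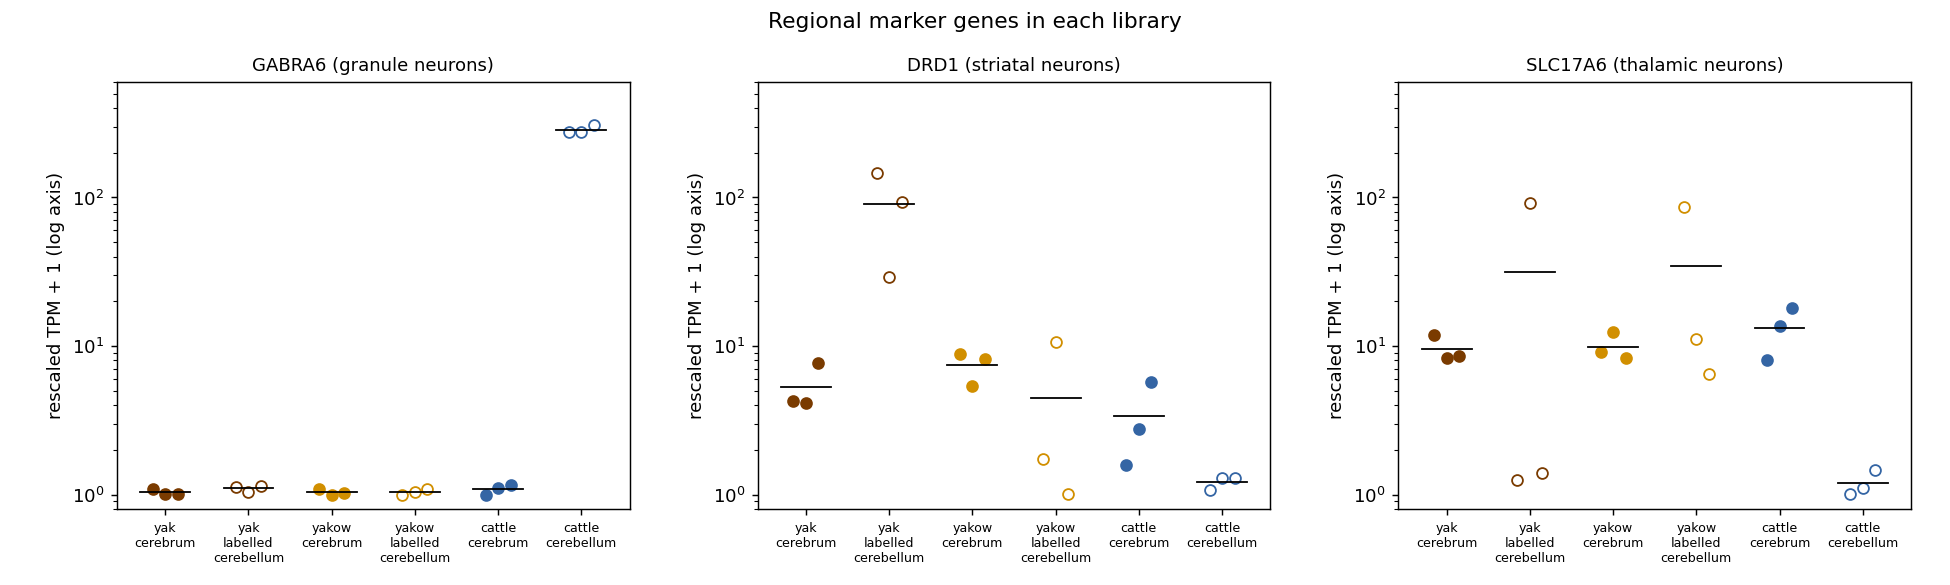
Rescaled TPM + 1 on a log axis of GABRA6, DRD1 and SLC17A6 in each library, by species, with filled points for cerebrum, open points for libraries labelled cerebellum and a line at the mean of each group of 3. GABRA6 is at 275 to 304.7 TPM in cattle cerebellum and at or below 0.1601 TPM elsewhere, while DRD1 reaches 146 TPM in yak labelled cerebellum 1 and SLC17A6 85.1 TPM in yakow labelled cerebellum 1.

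Yak and cattle cerebrum were compared to ask which genes differ between the plateau species and cattle in the same tissue. UGT8, an enzyme of myelin galactolipid synthesis, was higher in yak at 136.1 ± 40.4 against 36.2 ± 15.2 TPM (log2 fold change 1.93 ± 0.43 SE, adjusted p = 0.0102). RPL22, a ribosomal protein, was lower at 27.9 ± 3.01 against 90.4 ± 17.3 TPM (adjusted p = 0.00135). PGAM1, the phosphoglycerate mutase of glycolysis, was at 723.6 ± 71.2 against 314 ± 112.5 TPM (adjusted p = 0.0171, and 0.067 or 0.0848 without yak cerebrum 2 or cattle cerebrum 2). DNAJA1, a cochaperone of heat shock proteins, was at 92 ± 4.1 against 38.4 ± 2.67 TPM (adjusted p = 0.0124, and 0.0503 without cattle cerebrum 2). The largest changes were in genes known by locus number: LOC102273856 at 0.907 ± 0.545 against 76.6 ± 17.6 TPM (adjusted p = 9.71e-08) and LOC106700735 at 0.187 ± 0.239 against 21.4 ± 0.958 (adjusted p = 1.85e-05) were lower in yak. LOC102281485 was listed at 13.4, 0 and 0 TPM in the yak libraries and at 76.8, 1211 and 991.4 in cattle (adjusted p = 0.000608). LOC102265128 and LOC102282866 stood at 70.8 ± 15 and 27.7 ± 5.73 TPM in yak and were listed at 0 in cattle. BORCS6, a subunit of a complex that positions lysosomes, was at 24.2 ± 3.01 TPM in yak and listed at 0 in cattle (adjusted p = 0.019). The call was lost without yak cerebrum 2 (0.0623) or 3 (0.0619) or cattle cerebrum 1 or 2 (0.0588 each).

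Of the oxygen and energy lists, the altitude candidates were called as a list between yak and cattle cerebrum. Of these 18 genes 2 rose in yak, 3 when adjusted over the list alone (adjusted p = 0.0303, and adjusted p = 0.323 with an estimated correlation, 0.0967 without yak cerebrum 2, and 0.227 against symbols alone). GLUL, the glutamine synthetase of astrocytes, was at 3962 ± 799.8 against 2249 ± 215.1 TPM (adjusted p = 0.0386, and between 0.0808 and 0.154 without yak cerebrum 2 or 3 or any cattle cerebrum library). TGFBR2, a receptor of transforming growth factor beta, was at 30.2 ± 8.42 against 15.6 ± 9.42 TPM (adjusted p = 0.0495, and 0.192, 0.115, 0.188 and 0.154 without yak cerebrum 2 and 3 and cattle cerebrum 1 and 3). Its direction turned to -0.37 with annotated transcripts only. NDRG1, a hypoxia-induced protein of myelinating cells, was at 284.4 ± 76.3 against 124.9 ± 17.1 TPM (adjusted p = 0.0223), the 1 of 25 hypoxia targets called (list adjusted p = 0.151). The call was lost without yak cerebrum 2 (0.102) or 3 (0.0781) or cattle cerebrum 1 (0.0855) or 2 (0.0647). VEGFA, the vascular growth factor, was at 27.8 ± 10.5 against 8.08 ± 3.05 TPM and was not called. No gene of the 13 in the hypoxia-inducible factor pathway was called (list adjusted p = 0.337), nor any of the 3 globins, NGB standing at 16.4 ± 1.68 against 29.9 ± 10.7 TPM. Of 17 glycolysis genes 2 rose, PGAM1 and the lactate exporter SLC16A3 (list adjusted p = 0.0516). SLC16A3 was lost without yak cerebrum 2 (0.0997) or 3 (0.0665) or cattle cerebrum 1 (0.0711) or 2 (0.0615). Of 45 respiratory chain genes 2 rose and 1 fell (0.144). The antioxidant list of 27 genes had 1 member down (adjusted p = 0.0572).

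Oligodendrocyte markers were higher in yak cerebrum than in cattle: 2 of 14 rose, 3 when adjusted over the list alone (adjusted p = 0.00321, and adjusted p = 0.918 with an estimated correlation). MAG, a myelin adhesion protein, was at 326.6 ± 99.4 against 128.5 ± 23 TPM (adjusted p = 0.0251, and 0.108, 0.0906, 0.0985 and 0.0672 without yak cerebrum 2 and 3 and cattle cerebrum 1 and 2). The list's mean level was 6.52, 7.78 and 7.5 log2 units in the yak libraries and 6.51, 6.31 and 6.36 in the cattle ones, so NDRG1, UGT8 and MAG moved beside a myelin signal that yak cerebrum 1 did not share. P2RY12, a purinergic receptor of microglia, was at 22 ± 8.23 against 6.88 ± 1.43 TPM (adjusted p = 0.019), a call lost without yak cerebrum 2 (0.0751) or 3 (0.0874) or cattle cerebrum 2 (0.0652). Heat shock genes, 2 of 20 up and 2 up with 1 down when adjusted over the list alone, were called at adjusted p = 0.0468 (adjusted p = 0.918 with an estimated correlation). That list stood at 0.0506, 0.171, 0.118 and 0.0591 without yak cerebrum 1 and 2 and cattle cerebrum 1 and 2. Ribosomal protein genes had 3 up and 1 down of 64, 1 down when adjusted over the list alone, at adjusted p = 0.0468 (adjusted p = 0.918 with an estimated correlation). They stood at 0.171, 0.0967 and 0.135 without yak cerebrum 2 and cattle cerebrum 2 and 3. Against symbols alone, whose median was 0.14 log2 units, the heat shock and ribosomal calls ended (0.43 and 0.891). The ribosomal list's median of 0.1 turned to -0.07 with quantile normalization and -0.1 with FPKM. Of 20 immediate early genes 4 fell, 7 when adjusted over the list alone, and of 23 interferon genes 2 fell, 5 when adjusted over the list alone. Neither list was called against all loci (0.144 and 0.114), and both were lower in yak against symbols alone (1.4e-05 and 2.16e-06). Against all loci both had adjusted p = 0.918 with an estimated correlation, which was not run against symbols alone.

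In total 1216 loci were higher in yak cerebrum and 2367 lower, and 2154 of the lower ones had no name. Among symbols the split ran the other way, 425 higher and 122 lower, and with quantile normalization it was 1532 to 1287 over all loci. Leaving out yak cerebrum 2 or 3 or cattle cerebrum 1 or 2 reduced the 3583 calls to 1635, 1674, 1734 or 1724. Within lane 4, which held the 3 yak and 2 of the cattle libraries, 1025 loci were called. The 3583 loci had a median fold of 1.34 log2 units there in the direction called, against 1.39 over all lanes. These libraries also helped to choose the loci, so that agreement cannot decide on lane.

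In yakow against cattle cerebrum, the called genes included a pair of hypoxia targets and 3 oligodendrocyte genes that were higher in yakow and 4 immediate early genes that were lower. VEGFA was at 54.3 ± 32.5 against 8.08 ± 3.05 TPM (log2 fold change 2.47 ± 0.64 SE, adjusted p = 0.0423). NDRG1 was at 297.7 ± 74.7 against 124.9 ± 17.1 TPM (1.22 ± 0.3, adjusted p = 0.0318). These were the 2 of 25 hypoxia targets called. The hypoxia list was called at adjusted p = 0.00207 (adjusted p = 0.315 with an estimated correlation, and 0.172 against symbols alone), its call kept without each of the 6 libraries. FOS, an immediate early transcription factor, fell from 33.2 ± 11 TPM in cattle to 6.84 ± 0.424 in yakow (adjusted p = 0.00705). FOSB and EGR2 were at 4.66 ± 2.26 and 1.81 ± 2 TPM against 16.7 ± 2.05 and 7.88 ± 3.28 (adjusted p = 0.0441 and 0.046). Of 20 such genes 4 fell, 9 when adjusted over the list alone (adjusted p = 0.00176, and adjusted p = 0.671 with an estimated correlation). Of 14 oligodendrocyte markers 3 rose, 4 when adjusted over the list alone (adjusted p = 0.000183, and adjusted p = 0.824 with an estimated correlation). UGT8 was at 163.2 ± 73.7 against 36.2 ± 15.2 TPM (adjusted p = 0.0131) and MAG at 358.5 ± 190.1 against 128.5 ± 23 (adjusted p = 0.0381). The oligodendrocyte list's mean level was 7.77, 6.44 and 7.78 log2 units in the yakow libraries, and that of the immediate early list 2.59, 3.18 and 2.62 against 3.72, 3.61 and 3.68 in cattle. SOX10, a transcription factor of the oligodendrocyte lineage, was at 182 ± 77.9 against 69.2 ± 10.3 TPM (adjusted p = 0.0243).

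Single libraries decided many of these yakow calls. VEGFA was lost without yakow cerebrum 1 (0.13) or 2 (0.121) or any cattle cerebrum library (0.112, 0.0862 and 0.0837), and NDRG1 without yakow cerebrum 1 (0.11) or 3 (0.119) or cattle cerebrum 1 (0.113) or 2 (0.0979). UGT8 was lost without yakow cerebrum 1 (0.057) or 3 (0.068), and MAG without those (0.102 and 0.146) or cattle cerebrum 1 (0.133) or 2 (0.106). SOX10 was lost without yakow cerebrum 1 (0.0792) or 3 (0.107) or cattle cerebrum 1 (0.0507) or 2 (0.0875). FOSB and EGR2 were lost without yakow cerebrum 1 (0.145 and 0.16) or 3 (0.141 and 0.163) or any cattle cerebrum library (between 0.0764 and 0.12), while FOS kept its call. No member of the hypoxia-inducible factor, altitude, glycolysis or respiratory chain lists was called, with the altitude list at adjusted p = 0.0634. Against symbols alone calcium signalling (0.00477) and interferon genes (0.0176) were lower in yakow, both lists at 0.841 against all loci and adjusted p = 0.968 with an estimated correlation. By locus number, LOC102265128 and LOC102270035 stood at 60.5 ± 12.5 and 8.87 ± 1.04 TPM in yakow and were listed at 0 in cattle, and LOC102282834 was listed at 0 in yakow and stood at 80.8 ± 20.8 TPM in cattle. In total 262 loci were higher in yakow and 1136 lower, 137 and 30 among symbols, and the split was 432 to 706 with quantile normalization. Hardly any gene was called with named genes only or with annotated transcripts only, and far fewer loci with limma-voom. The split among symbols therefore held only in the test over all loci, and the counts are given with the processing below. The 1398 calls fell to 357, 876 or 415 without yakow cerebrum 1, 2 or 3 and to 527 or 382 without cattle cerebrum 1 or 2.

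Yak and yakow cerebrum differed in 206 genes with a symbol and 105 with a locus number. PGAM1 was higher in yak at 723.6 ± 71.2 against 258.6 ± 44 TPM (log2 fold change 1.49 ± 0.31 SE, adjusted p = 0.00886). RAB33A, a vesicle traffic protein of neurons, was also higher at 27.7 ± 2.87 against 0.463 ± 0.275 (4.31 ± 0.84, adjusted p = 0.00657). LOC102273856 was at 0.907 ± 0.545 TPM in yak and 71.4 ± 10.6 in yakow (adjusted p = 1.38e-07), and LOC102281485 at 13.4, 0 and 0 in yak and 1094 ± 113.2 in yakow (adjusted p = 0.000181). LOC102282866 stood at 27.7 ± 5.73 TPM in yak and was listed at 0 in yakow. NDUFA2, a subunit of respiratory complex I, was at 184.9 ± 40.1 against 31.6 ± 36.5 TPM (adjusted p = 0.0341), a call lost without any yak cerebrum library (0.118, 0.0878 and 0.087) or yakow cerebrum 2 (0.136) or 3 (0.157). No list was called. Of 1428 loci 720 were higher in yak and 708 lower, with 105 and 101 among symbols, and the count was 950, 944 or 934 without yak cerebrum 2, yak cerebrum 3 or yakow cerebrum 1. Each group came from its own lane, and 239 loci were called with lane as a covariate.

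**Figure D3:**
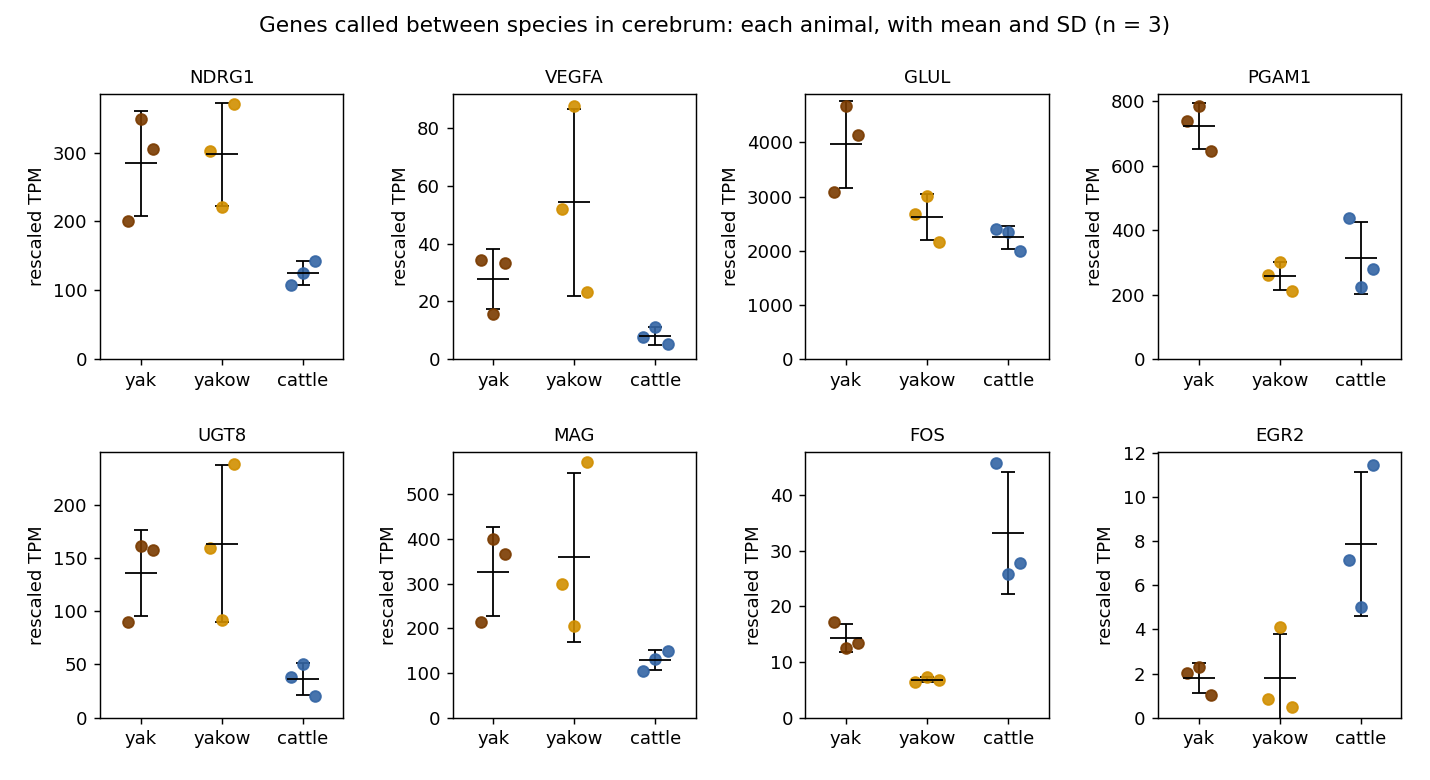
Rescaled TPM (vertical axes from 0) in cerebrum of NDRG1, VEGFA, GLUL, PGAM1, UGT8, MAG, FOS and EGR2 for yak, yakow and cattle, with 1 point per animal and a bar for the mean ± SD (n = 3; the lower bar of EGR2 in yakow is clipped at 0). NDRG1, GLUL, PGAM1, UGT8 and MAG were called between yak and cattle, NDRG1, VEGFA, UGT8, MAG, FOS and EGR2 between yakow and cattle, and PGAM1 between yak and yakow.

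The species comparisons of the libraries labelled cerebellum set yak and yakow libraries low in granule and Purkinje markers against cattle cerebellum. The patterning list was at the cattle level in yak labelled cerebellum 2 and yakow labelled cerebellum 1. FAT2 and GABRA6 were lower in the yak libraries, at 0.265 ± 0.0444 and 0.0991 ± 0.0578 TPM against 482.4 ± 57.7 and 285.5 ± 16.7 in cattle (adjusted p = 5.16e-13 and 1.52e-13). DRD1, SST and BCL11B, a transcription factor of striatal and deep cortical neurons, were higher at 88.9 ± 59, 99.4 ± 46.5 and 60.4 ± 48 TPM against 0.219 ± 0.132, 0.305 ± 0.436 and 0.189 ± 0.0267. All 13 granule markers (adjusted p = 0.000559 with an estimated correlation) and 13 of 16 Purkinje markers (adjusted p = 0.00158 with an estimated correlation; 1 rose) were lower in the yak libraries. Higher in yak were 9 of 10 striatal (adjusted p = 6.28e-06), 10 of 14 oligodendrocyte (6.4e-05) and 9 of 11 microglia markers (4.68e-06). These stood at adjusted p = 0.317, 0.366 and 0.108 with an estimated correlation. Interneuron markers (6 of 14, adjusted p = 0.00141), ependymal markers (4 of 7, 0.00273), oligodendrocyte precursor markers (4 of 7, 0.00233), antigen presentation genes (5 of 8, 0.00549) and ribosomal protein genes (17 of 64, 4.15e-05) were higher too. With an estimated correlation these stood at adjusted p = 0.366, 0.366, 0.242, 0.421 and 0.845. When adjusted over the list alone, 9 interneuron markers rose and 1 fell, and 6 ependymal, 11 oligodendrocyte and 10 microglia markers rose, with the other lists unchanged in number.

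Of 18 altitude candidates 9 rose in yak in this comparison, and the list was called against all loci (9 up and 2 down when adjusted over the list alone, adjusted p = 0.0426, and adjusted p = 0.241 with an estimated correlation). EPAS1, the endothelial subunit of hypoxia-inducible factor, was at 149.4 ± 18.1 against 76.4 ± 10.7 TPM (adjusted p = 0.000627). EGLN1, the oxygen sensor that marks that factor for decay, was at 102.1 ± 12.7 against 57.3 ± 8.26 TPM, and GLUL at 3658 ± 821.9 against 1122 ± 55.8. Those 3 genes and NDRG1, at 268.9 ± 112.9 against 80.3 ± 11.9 TPM, kept their calls without each library, beside the regional markers that separate the same libraries. The 3 globins had 2 members up, 3 when adjusted over the list alone (adjusted p = 0.0335, and adjusted p = 0.212 with an estimated correlation). The endothelial list had 5 up and 1 down of 14, 7 up and 1 down when adjusted over the list alone (0.0228, and adjusted p = 0.421 with an estimated correlation). The altitude, globin and endothelial calls were lost without yak labelled cerebellum 2 (0.0837, 0.0837 and 0.0687) or cattle cerebellum 2 (0.0695, 0.0506 and 0.0669), and the endothelial call also without cattle cerebellum 3 (0.0526). Against symbols alone these 3 calls ended (0.348, 0.0931 and 0.159), and the patterning list was lower in yak (0.048, and 0.169 against all loci, with adjusted p = 0.845 with an estimated correlation). Of 25 hypoxia targets 3 rose and 2 fell (adjusted p = 0.906), CITED2, a transcriptional coregulator that competes with HIF1A, at 22.4 ± 3.72 against 80.9 ± 14.5 TPM. Of 8466 loci called, 4002 were higher and 4464 lower in yak. Among symbols the split ran the other way, 2123 higher and 1182 lower, against 1414 and 2951 among loci without a name.

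The yakow libraries labelled cerebellum differed from cattle cerebellum at 6094 loci, 2751 higher and 3343 lower, with 1492 and 1243 among symbols. The split was 3582 to 2070 with TPM as deposited, and the count was 2247 with lane as a covariate. All 13 granule markers and 13 of 16 Purkinje markers were lower (adjusted p = 0.000147 each with an estimated correlation), CALB1 at 0.357 ± 0.25 against 260.3 ± 56.8 TPM. NDRG1 was at 316.7 ± 56.4 against 80.3 ± 11.9 TPM and HK2, a hexokinase, at 5.79 ± 0.952 against 1.05 ± 0.269. HIF1A was lower at 90.3 ± 18.4 against 175.5 ± 23.7. It rose in cattle cerebellum, moved by 0.02 ± 0.23 log2 units between yakow tissues and was not called between yakow and cattle cerebrum. Of 14 oligodendrocyte markers 10 were higher in yakow, 12 when adjusted over the list alone (adjusted p = 9.62e-08). So were 5 of 7 precursor markers (0.00165), 7 of 11 microglia markers (1.81e-05) and 4 of 8 antigen presentation genes (0.00185). With an estimated correlation these lists stood at adjusted p = 0.291, 0.283, 0.155 and 0.448. The endothelial list had 5 up and 1 down of 14 (0.00465, and adjusted p = 0.396 with an estimated correlation). The mural list had 4 up of 12 (0.0104, adjusted p = 0.54 with an estimated correlation, and 0.182 without cattle cerebellum 3). The cortical (8 up, 1 down of 17) and interneuron lists (4 up, 1 down of 14) had adjusted p = 0.0104 each. With an estimated correlation they had adjusted p = 0.748 and 0.54. Both calls were lost without yakow labelled cerebellum 2 (0.162 and 0.068). Interferon genes (4 up, 1 down of 23, adjusted p = 0.0373, and adjusted p = 0.791 with an estimated correlation) were lost without that library (0.162) or cattle cerebellum 2 (0.116) or 3 (0.201). Ribosomal protein genes (3 up of 64, 0.0438, and adjusted p = 0.975 with an estimated correlation) lost their call without yakow labelled cerebellum 1 (0.772) or cattle cerebellum 2 (0.0783) or 3 (0.863, turning to lower). Against symbols alone the interferon and ribosomal calls ended (0.109 and 0.18), and respiratory chain genes were lower in yakow (0.0411, and 0.062 against all loci, with adjusted p = 0.975 with an estimated correlation). When adjusted over the list alone, 8 microglia, 6 antigen presentation, 9 endothelial, 11 cortical, 7 interneuron and 5 interferon genes were higher and 0 ribosomal protein genes by limma.

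Yak and yakow libraries labelled cerebellum differed at 2305 loci, 1303 higher in yak and 1002 lower (494 and 178 among symbols, and 813 to 1099 over all loci with FPKM), and at 1446 without yak labelled cerebellum 1 and 1460 with lane as a covariate. CDHR1 was at 282.1 ± 234.6 against 2.17 ± 0.702 TPM (adjusted p = 1.29e-05), and TAC1, the substance P precursor, at 93.3 ± 42.8 against 3.51 ± 1.18 (adjusted p = 0.00148). Of 10 striatal markers 8 were higher in yak, 10 when adjusted over the list alone (adjusted p = 7.56e-10, and adjusted p = 0.586 with an estimated correlation). Of 7 ependymal markers 3 were higher, 5 when adjusted over the list alone (0.000327, and adjusted p = 0.586 with an estimated correlation). Calcium signalling (4 of 33 up, adjusted p = 0.00532), respiratory chain (1 of 45 up, 0.00532) and ribosomal protein genes (2 of 64 up, 0.00425) were called as lists. Each had adjusted p = 0.854 with an estimated correlation, and they had 6, 0 and 0 members by limma when adjusted over the list alone. Against symbols alone these 3 calls ended (0.108 each), and the cortical and oligodendrocyte lists were lower in yak (0.0411 each, and 0.26 each against all loci, with adjusted p = 0.858 and adjusted p = 0.854 with an estimated correlation). The calcium call was lost without yak labelled cerebellum 1 (0.0821) or 3 (0.0669) or yakow labelled cerebellum 1 (0.19), and the respiratory call without yakow labelled cerebellum 3 (0.58). The ribosomal call was lost without yak labelled cerebellum 2 (0.101) or yakow labelled cerebellum 2 (0.0599) or 3 (0.266). RYR1, a calcium release channel, was at 20.4 ± 4.5 against 5.97 ± 6.66 TPM (adjusted p = 0.00942).

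Several lists were called in none of the 10 comparisons. Glutamate receptors (lowest adjusted p = 0.122), pan-neuronal markers (0.0842), astrocyte markers (0.393), choroid plexus markers (0.448), antioxidant genes (0.0513), glycolysis genes (0.0516) and the hypoxia-inducible factor pathway (0.337) were these. In cattle the glutamate receptor list had 5 members up and 5 down of 21, with a median of -0.49 and a mean of 0.08. The thalamic list, at adjusted p = 0.243, had a median of -0.42 and a mean of 0.17. Erythroid genes with 2 tested loci had 0 called in any comparison (limma; AHSP, the haemoglobin chaperone, at 2.53 ± 1.18 TPM in yak cerebrum and 2.98 ± 0.871 in cattle cerebrum). Of 2 hypothalamic and pituitary genes CGA, the hormone alpha subunit, was higher in the yak libraries labelled cerebellum by 1.1 ± 0.33 log2 units against cattle and 1.42 ± 0.33 against yakow. Its calls were lost without yak labelled cerebellum 1 (0.0751 and 0.0646) or 3 (0.103 and 0.0727), without cattle cerebellum 3 (0.0794) or without yakow labelled cerebellum 3 (0.0529). The single mitochondrial gene with its own locus, ND6, was at 280.4 ± 199 TPM in the yak libraries labelled cerebellum and listed at 0 in cattle cerebellum. It varied widely within groups, at 5.08, 4.03 and 0.1 log2 units in yak cerebrum. In yakow it stood at 3.44, 0 and 0 in cerebrum and 4.58, 0 and 0 in the libraries labelled cerebellum. Mitochondrial loci held at most 0.096% of TPM in any library.

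The yakow's position between its parent lineages was measured as its distance from cattle divided by the distance of yak from cattle. Over 3576 genes called between yak and cattle in cerebrum and measured in the libraries labelled cerebellum, the median position was 0.29 (interquartile range -0.13 to 0.78), and 39.3% were nearer yak. Over 8447 genes called in the libraries labelled cerebellum and measured in cerebrum it was 0.6 (-0.01 to 1.17), with 53.7% nearer yak, and the SD over the 3 yakow animals was 0.11 and 0.04. Both use libraries labelled cerebellum that carried different regional markers in yak and yakow. The former fell to 0.14, 0.13 or 0.17 without yak 2, yak 3 or cattle 2 and was 0.51 over 547 symbols, and the latter ranged from 0.5 to 0.74 with both libraries of an animal left out. Noise alike in the 3 species, with no difference between them in the tissue measured, would also give a median near 0.5. The medians of 0.6 and 0.51 alone therefore do not place the yakow between its parents. Of 1748 loci called between yak and cattle in both tissues, 1714 had the same sign (98.1%, exact binomial interval 97.3 to 98.6). That interval takes loci as independent and does not measure the spread over animals. Independent lists would share 165.5 higher and 359.3 lower loci against 868 and 846 observed, but the tissues share animals, so the lists are not independent. Among symbols 284 of 297 had the same sign.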

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

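The tests of a label swap, of another brain region, of a uniform species difference and of symbols higher in cattle were chosen only after the result was seen. The tissue difference differed among species at 1870 of 29412 tested loci, and at 792 of the 11317 with a symbol, by a moderated F test of limma. The 10 named genes with the smallest p were GABRA6 (adjusted p = 2.01e-11), FAT2 (2.07e-10), CBLN3 (2.53e-09), CDH15 (1.01e-08), PCP2 (8.61e-08), IL16, ZP2 and SKOR1 (1.01e-07 each) and LOC106701121 and CFAP74 (4.06e-07 each). Of the lists, 12 of 13 granule, 12 of 16 Purkinje, 4 of 8 patterning, 7 of 21 glutamate receptor, 5 of 33 calcium signalling, 3 of 17 cortical, 3 of 10 striatal, 3 of 7 ependymal, 3 of 11 microglia and 3 of 14 endothelial genes differed so. With 2 members each stood GABA receptors, thalamic and astrocyte markers, and with 1 each the hypoxia-inducible factor pathway, altitude candidates, heat shock, immediate early, interferon, globin, interneuron, oligodendrocyte precursor, mural and ribosomal protein genes. Among the genes named by rule, the difference held for 10 of 12 in the yak tissue comparison, 24 of 50 in cattle and 16 of 32 over species. In cerebrum it held for 5 of 29 between yak and cattle, 2 of 14 between yak and yakow and 2 of 19 between yakow and cattle, and in the libraries labelled cerebellum for 29 of 72, 12 of 31 and 21 of 65. Of 100 drawn divisions of the 9 animals into 3 species, 1, the real one, gave as many loci, and the highest other gave 1488. The other divisions mix species within groups, which adds species differences in level to the spread and can lower the calls. The test therefore favours the real division and cannot exclude chance as the cause of that count.

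The 6 yak and yakow libraries labelled cerebellum lay far below cattle cerebellum in granule and Purkinje markers. The patterning list was near the cattle cerebellum level in yak labelled cerebellum 2 and yakow labelled cerebellum 1. A swap with the cerebrum groups is excluded if GABRA6 was counted in yak and yakow reads. That gene reached at most 0.0923 TPM in yak and yakow cerebrum against 275 to 304.7 TPM in cattle cerebellum. A failure to count cerebellar genes in those reads is excluded as a general cause only for genes also present in cerebrum. These were 127 symbols at least 4-fold higher in cattle cerebellum and with a mean of at least 1 TPM in cattle cerebrum. Their median in cerebrum was 0.1 log2 units in yak and -0.02 in yakow against cattle. For genes below that level, GABRA6 among them, such a failure was not tested and stays open. A species difference alike in all animals would give like levels of the region lists within a species. The striatal list spanned 4.42 log2 units in the yak libraries labelled cerebellum (0.36 in yak cerebrum) and 0.79 in those of yakow, so that list alone could not decide. The widest of the cortical, striatal and thalamic lists spanned 4.42 in yak (striatal) and 3.5 in yakow (cortical, 0.64 in yakow cerebrum). Each span came through 1 library, yak labelled cerebellum 2 (3.57) and yakow labelled cerebellum 1 (1.69), and taking the widest list favours a large span. The values argue against such a difference as the cause of the region lists' levels in all 6 libraries together. It stays open for the other 4 libraries and for granule and Purkinje markers, low in all 6. In 6 of 6 libraries a cortical, striatal or thalamic list stood at least 1 log2 unit above the highest cattle cerebellum library, by 5.39, 1.62 and 4.99 in yak and 1.64, 2.22 and 1.57 in yakow, and a candidate explanation is tissue taken from another brain region. That was found and tested on the same data, it was not tested which region holds both thalamic and patterning genes in those 2 libraries, and an exchange with samples outside the series was not tested.

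Of the loci without a name, 2154 were higher in cattle than in yak cerebrum. Over all 14813 loci without a name, those of 1 exon lay at -0.05 log2 units from those of more exons. Without single libraries that value was -0.09 to -0.04. Both kinds lay below symbols, with medians of -0.52 and -0.47 against 0.14. Among the 2154, 67.2% had 1 exon and 64.7% no strand. These shares were 60.5% and 53.8% of those not called, and 67.7% and 63.9% of those higher in yak. The values argue against unspliced or genomic RNA that raises 1-exon loci alone, but such RNA raising both kinds stays open. With aligned bases as a covariate 404 stayed called, but symbols went from 547 to 88 as well, the median fold of the 2154 moved from -1.41 to -1.12 log2 units (SE 0.35 and 0.42) and that of all 14813 loci without a name from -0.5 to -0.23, so depth cannot be told apart from species. Over 18 libraries the number of such loci at 1 TPM fell with aligned bases within groups (r = -0.64, permutation p = 0.042; rho = -0.63, permutation p = 0.0326; 1 relation computed), with r = -0.49 without the 2 farthest libraries. A species difference stays open and untested.

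Yak and cattle cerebrum differed at 3583 loci, and 1025 were called within lane 4, where the same 5 libraries gave 1734 in a fit with the other lanes, so by this count lane cannot be told apart from the loss of a library. Within lane 4 the median fold of the 3583 loci was 1.34 log2 units (quartiles 1.05 and 1.72, SE 0.35) in the direction called, against 1.39 over all lanes. The same 5 libraries helped to choose these loci, so the agreement was favoured in advance and cannot decide on lane. A second set of loci was chosen between yak cerebrum 1 (lane 4) and cattle cerebrum 1 (lane 3), 1 library each, with the spread taken from the other groups. Most loci of this second set were also among the 3583. The median fold of the second set was 3.19 log2 units between the libraries that chose it. In yak cerebrum 2 and 3 against cattle cerebrum 2 and 3 (all lane 4) it was 2.09 (SE 0.34) in the direction chosen. Lane number as the whole cause is thus excluded for this second set of loci as a set. The flow cell is not known. A loss of cattle reads on a yak reference is excluded as the whole cause of the 547 called symbols, since it would lower cattle and 122 were higher there, at a median of -1.21 log2 units (SE 0.28), but how many reads aligned was not measured. For the 425 higher in yak it cannot be told apart from a species difference, since the yakow stood at a median position of 0.55, which both would give. A biological difference between the species stays open.

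For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split and the highest of the others gave 120 and 11 loci for tissue in yak, 5177 and 3 in cattle, and 0 and 36 in yakow (limma; 990 loci at an unadjusted p below 0.05, voom 0). In cerebrum they gave 3583 and 2 for yak and cattle, 1428 and 2 for yak and yakow and 1398 and 4 for yakow and cattle, and in the libraries labelled cerebellum 8466 and 2, 2305 and 333, and 6094 and 307. The real split was the 1 of 10 with as many loci in each case except yakow tissue, where 10 of 10 had as many. Over the 3 species 2 of 100 drawn swaps of tissue labels within animals gave as many loci as the real 1777, the real one and a swap of yakow 2 and 3, the highest other with 1860. The 27 drawn swaps that kept the cattle labels together gave 388 to 1860 loci and the 72 that parted them 0 to 4. The count thus followed the cattle labels. Swaps among 3 cattle animals are too few for a share under 0.05, so chance is not excluded for the labels of any species.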

How the results depend on the processing

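The alternatives chosen only after the data were seen are annotated transcripts only, lane as a covariate, lane 4 alone, the fit without the 6 libraries labelled yak or yakow cerebellum, set tests among symbols, and the position in the same tissue or over symbols. Of 6172 values of named genes under other settings, 5311 kept direction and side of the threshold, 834 lost the call in the same direction, 5 gained it and 22 reversed. With a library left out, 2853 of 3414 kept both, 559 lost the call, 2 gained it and 0 reversed. Where not stated, the cause of a move was not tested. Depth in reads is not known, so what it limits cannot be stated in counts.

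With TPM as deposited, yakow and cattle cerebrum differed at 890 loci in place of 1398. With FPKM the counts were 2331 for yak and cattle cerebrum and 651 for yakow and cattle cerebrum, and with a pseudocount of 0.1 the latter was 379. With TPM as deposited the median of all loci moved from -0.044 to -0.27 in the cattle tissue comparison, from 0.004 to -0.107 over species, from -0.048 to -0.155 between yak and yakow labelled cerebellum and from -0.007 to 0.172 between yakow and cattle labelled cerebellum. With a filter of TPM at least 5 in at least 3 libraries, which tests fewer loci, the counts were 3094 for tissue in cattle, 948, 729 and 111 in cerebrum (yak and cattle, yak and yakow, yakow and cattle), 4912 and 1325 in labelled cerebellum (yak and cattle, yak and yakow) and 1170 for the interaction. With limma-voom they were 8 for tissue in yak, 2334 for yak and cattle cerebrum and 355 for yakow and cattle cerebrum, and RPL15 (yak and cattle cerebrum), BNIP3 (yak and yakow labelled cerebellum) and RPL38 (yakow and cattle labelled cerebellum) reversed to -0.6, 0.16 and -0.26.

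With arrayWeights the counts were 591, 10775 and 3073 for tissue in yak, in cattle and over species, 7826, 2638 and 5792 in cerebrum, 13308 for yak and cattle labelled cerebellum and 5195 for the interaction, with cattle cerebellum 2 at a weight of 5.43 and the others between 0.4 and 2.29. With only the libraries of the groups compared, which leaves fewer samples, they were 25 and 4 for tissue in yak and yakow, and 5396, 614 and 2527 in labelled cerebellum. With a fold threshold the count over species was 578. With named genes only, which tests fewer genes, the counts were 2806 for tissue in cattle, 342, 226 and 6 in cerebrum, 4183, 802 and 3601 in labelled cerebellum and 1058 for the interaction, and 96.9% of loci called in both tissues had the same sign. The 342 split into 227 higher and 115 lower, and the 6 into 3 and 3.

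With annotated transcripts only, the counts were 34, 2 and 895 for tissue in yak, yakow and cattle, 336 over species, 192, 192 and 2 in cerebrum, 1842, 399 and 1264 in labelled cerebellum and 226 for the interaction. In the cattle tissue comparison ARNT2, PRKCD and ADARB1 reversed to 1.44, -0.29 and -0.18, and over species MAP3K1, SDK1 and ARNT2 to -0.21, 0.32 and 0.89. TGFBR2 reversed to -0.37 (yak and cattle cerebrum) and ENPP2 to -0.05 (yakow and cattle cerebrum). In labelled cerebellum PSMB8, PRLR and BCAS1 reversed to -0.22, -0.32 and -0.43 (yak and cattle), NDUFA12 and RYR3 to -0.71 and -0.16 (yak and yakow), and ARNT2 and PRLR to -2.12 and -0.19 (yakow and cattle). With lane as a covariate the counts were 195, 12 and 2290 for tissue in yak, yakow and cattle, 110 over species, 239 for yak and yakow cerebrum, and 1460 and 2247 for yak and yakow and for yakow and cattle labelled cerebellum. MX1 reversed to 0.02 (tissue in cattle), and LOC102266067 and FAM212B to 0.75 and 0.26 (yak and yakow cerebrum). Within lane 4, with fewer samples, yak and cattle cerebrum gave 1025. Tissue in cattle gave 990 there, with MX1 at 0.02, for 2 cerebrum libraries against 1 of cerebellum, which is assumed to vary like the other groups. Without the 6 libraries labelled yak or yakow cerebellum, tissue in cattle gave 5951 and yak and cattle cerebrum 3818.

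With the animal as a replicate block, tissue in yak gave 38 loci and tissue in yakow 2. In yak TAC1 (adjusted p = 0.0519), LOC102265128 (0.0657), VIP (0.0943), FEZF2 (0.0632), DRD1 (0.0971) and SYT9 (0.0665) lost their calls, and over species HIF1A (0.0539), NPAS4 (0.0556) and MB (0.0578). In cattle TTR (0.0287), antigen presentation genes (0.0304) and oligodendrocyte markers (0.0274) gained a call, as did GABA receptors (0.0492) and mural markers (0.0126) over species, and the block changed no other call of a named gene or list. For species comparisons the replicates share only a number. With that number as a block the counts were 3165, 1284 and 1141 in cerebrum and 7918, 2003 and 5449 in labelled cerebellum, and same-numbered libraries correlated between -0.127 and 0.168, not every library best with its own number.

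Of 310 tests of gene lists, 74 were called with the preset correlation, 8 with the estimated correlation, 52 by fry and 65 against symbols alone, 55 of these in both. The position of the yakow measured in the same tissue was 0.6 and 0.72 for loci called in cerebrum and in labelled cerebellum, and 0.51 over symbols for the former. With a library left out, the counts ranged from 31 to 515, 0 to 2 and 3552 to 4724 for tissue in yak, yakow and cattle, 1272 to 2071 over species, 1635 to 3808, 934 to 1071 and 357 to 1957 in cerebrum, 6255 to 9048, 1446 to 2627 and 4079 to 6278 in labelled cerebellum and 1072 to 2557 for the interaction. With both libraries of an animal left out, the position ranged from 0.13 to 0.39 for loci called in cerebrum and from 0.5 to 0.74 for those called in labelled cerebellum.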

Other observations

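The genes below were chosen after their values were seen, from 284 symbols called in the same direction between yak and cattle in both cerebrum and the libraries labelled cerebellum. In cerebrum TF, the iron carrier transferrin, was at 1030 ± 173 TPM in yak, 706 ± 185 in yakow and 327 ± 47.4 in cattle (SD, n = 3; limma adjusted p = 0.0091 between yak and cattle), and GLO1, the glyoxalase that clears methylglyoxal, at 53.7 ± 3.08, 18.9 ± 5.85 and 15.3 ± 8.75 TPM (adjusted p = 0.0029). Oligodendrocytes are a main source of TF in brain, and their marker list was higher than in cattle in yak cerebrum (camera adjusted p = 0.00321, and adjusted p = 0.918 with an estimated correlation) and in yakow cerebrum (0.000183, and adjusted p = 0.824 with an estimated correlation). EFHD1, a mitochondrial calcium-binding protein, was at 270 ± 82.1 TPM in yak and 72.6 ± 20.3 in cattle (adjusted p = 0.00349). Lower in yak were LYRM4, a partner of the mitochondrial iron-sulphur cluster desulphurase, at 12.4 ± 1.49 TPM against 52.1 ± 6.4 in yakow and 60.3 ± 19.5 in cattle (adjusted p = 8.27e-05), TIMM10, a chaperone of mitochondrial protein import, at 13.5 ± 3.36 against 50.2 ± 9 and 39 ± 5.38 TPM (adjusted p = 0.000397), and SNRPD1, a core spliceosomal protein, at 9.81 ± 1.52 against 36.5 ± 5.24 and 35.8 ± 0.867 TPM (adjusted p = 0.000144). Between yakow and cattle cerebrum LYRM4 (0.781), TIMM10 (0.362), SNRPD1 (0.986), GLO1 (0.58), EFHD1 (0.292) and TF (0.0915) did not pass the test.

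Among loci without a name, 67.2% of the 2154 called lower in yak cerebrum had 1 exon, with a median length of 512 bases, against 60.5% and 692 bases of those not called, and 67.7% and 550 bases of the 684 called higher in yak.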
